A study of Drosophila melanogaster with 12 samples.

How the data were processed

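RNA was sequenced from whole adult Drosophila melanogaster, 5 flies per biological replicate, in a 2 × 2 design with 3 replicates per group. Flies of the control strain w1118 and of an Akh mutant strain (allele AkhA) were injected with phosphate-buffered saline (PBS) or with Drosophila C virus (DCV). Akh encodes adipokinetic hormone, the fly hormone that mobilises stored fat and sugar. Per the labels, w1118 flies were collected 5.5 days and Akh mutants 3.5 days after injection, so every comparison between genotypes is also one between collection days. The labels give neither the sex of the flies nor a sequencing batch.

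The authors provided one table of expected counts (estimated reads per gene), unscaled for depth or length. The labels list fastp 0.21.0, STAR 2.7.9a, RSEM without a version and the dm6 genome build, with no order or settings. The deposited values are expected counts with 2 decimals, and between 10.9 and 12.0% of the values in each library were not whole numbers, as estimates from shared reads can be. The table holds 14167 features: 13953 with FlyBase gene identifiers, of which 13946 matched a symbol and 7 did not, and 214 unnamed features that the authors added. Positions are from the Ensembl annotation of the same genome assembly, counted from 1. The table held no viral features, so viral RNA was not analysed here.

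Library totals ranged from 17.12 to 19.0 M expected counts (M, 1e6). Counts were rounded to whole numbers. Genes were kept by filterByExpr of edgeR (minimum count 10, minimum total 15), which left 10266. They were scaled by trimmed mean of M values (TMM) and tested with robust quasi-likelihood F tests in edgeR 4.0.16, in R 4.3.3, in one model of the 4 group means over all 12 libraries with 8 residual degrees of freedom. The biological coefficient of variation was 9.1%. A gene was called at a Benjamini-Hochberg adjusted p under 0.05, and the number changed at least 2-fold is given beside each count. Tests were two-sided. The 5 comparisons were DCV against PBS in each genotype, the difference between those responses (Akh mutants minus w1118, an interaction term), and Akh mutants against w1118 after PBS and after DCV. Errors beside log2 fold changes are approximate standard errors. Each is the absolute log2 fold change divided by the square root of the F statistic of its test, so it restates that test. Errors beside CPM (counts scaled to library depth by edgeR) are SD over n = 3 libraries.

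The gene lists were written from general knowledge before the data were examined. Of the 42 lists, 40 had at least 3 tested members. They cover Akh and insulin signalling, lipid mobilisation, lipid synthesis, beta oxidation, trehalose and glycogen, glycolysis, the tricarboxylic acid cycle, oxidative phosphorylation, mitochondrial genome, cytosolic and mitochondrial ribosome, ribosome biogenesis, tRNA synthetases, proteasome, heat shock, endoplasmic reticulum stress, ATF4 and serine synthesis, autophagy, redox, detoxification, apoptosis and JNK, JAK-STAT, Imd and antimicrobial peptides, Toll, antiviral RNA interference and STING, haemocytes and melanisation, digestive enzymes, fat body, muscle, neurons, photoreceptors, odorant binding, cuticle, clock, histones, DNA replication and cell cycle, early female germline, eggshell, yolk, testis, seminal fluid, and genetic background markers. Testis and seminal fluid genes each had only 2 members past the filter, of 16 and 51 in the table, and were not tested. Lists were tested with camera of limma 3.58.1 at a preset correlation between genes of 0.01 on log2 CPM (prior count 2), with p adjusted over the 40 lists. Camera with an estimated correlation and fry were run beside it.

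A rule for genes to be named was fixed before the data were examined. It gave 179, 174, 135, 39 and 39 genes for the 5 comparisons in the order above. The text names only a part of these, chosen after the results were seen. The rule takes the 8 higher and the 8 lower genes with the largest log2 fold change in each comparison, with mean CPM of at least 5 and, outside the interaction, no overlap between the libraries compared. It adds up to 4 called members per list with the smallest adjusted p in the infection comparisons and the interaction, and Akh, AkhR, w and all members of the Akh and insulin and the lipid mobilisation lists. Genes known only by a CG or similar number count among the 8 but are named only within the first 3 of their direction. Where a group had 0 counts, folds are lower bounds against a floor of 3 counts over the group. With 1 to 3 counts a ratio with its 95% counting interval is given. Intervals and floors cover counting error only.

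The procedure was tested on simulated data. For DCV against PBS in w1118, 90% of genes changed 2-fold and 72% of those changed 1.5-fold were recovered in a step with 10115 genes, with 3.23% false calls. For the interaction, 80% and 40% were recovered in a step with 10099 genes, with 6.51% false calls. The simulations gave all genes and libraries the same spread between replicates and changed 50 genes at each fold, in random directions. In the data far more genes were called and the groups differed in scatter, so these rates need not hold there. The alternatives were DESeq2 1.42.0, limma-voom, size factors of DESeq2 within edgeR (RLE), no low-count filter, a filter of 5 CPM in 3 libraries, the replicate number as a block, only the libraries compared, removal of the 20 most abundant genes, and omission of each library in turn. Omission of each library while the same genes were tested was added after the data were seen. Replicate numbers did not pair libraries across groups: of 18 residual correlations, from -0.21 to 0.18, 2 were above 0.1. Labels of Gene Ontology terms came from the deposited annotation column, with term sizes counted among 9219 annotated tested genes and terms of 10 to 500 genes tested with the hypergeometric test.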

Results

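Whole-body RNA was measured in 4 groups of 3 libraries: w1118 after PBS, w1118 after DCV, Akh mutants after PBS and Akh mutants after DCV. Mean depth was 18.98 M ± 0.03 expected counts for w1118 after PBS and 17.4 M ± 0.25 after DCV (SD, n = 3 each). It was 18.83 M ± 0.12 for Akh mutants after PBS and 17.33 M ± 0.05 for Akh mutants after DCV (SD, n = 3 each). Infected groups thus had the smaller totals. The series title puts the question as the part Akh plays in the changes of gene expression across the body that this virus causes.

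The Akh gene itself (FBgn0004552, chromosome 3L, 4141467 to 4142070) separated the genotypes. It had 229 counts over the 6 w1118 libraries, between 31 and 56 in each, and 4 counts over the 6 mutant libraries, 0 or 1 in each. Scaled for depth, the ratio of w1118 to mutants was 56.6, with a counting interval of 21.8 to 209. On the first principal component of all genes (61.1% of variance) the PBS libraries lay between -68.7 and -41.5 and the DCV libraries between 16 and 76.1. The second (24.1%) parted the genotypes, from -46.3 to -20.9 in w1118 and from 23.1 to 47.1 in Akh mutants. Infected Akh mutants were the most scattered group, with 52.8, 16 and 38 for replicates 1, 2 and 3 on the first component. Replicate 2 was the nearest to the PBS libraries.

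**Figure D1:**
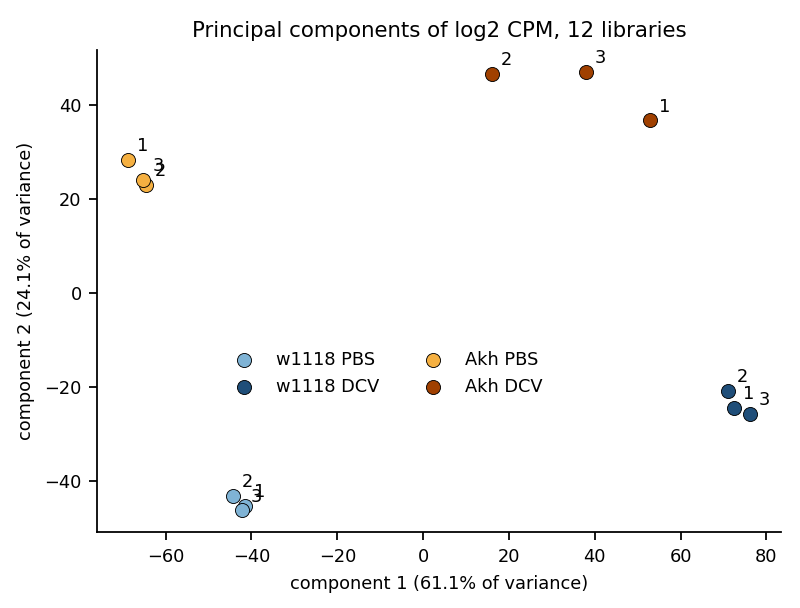
Principal components 1 (horizontal) and 2 (vertical) of log2 CPM for the 12 libraries, in arbitrary units, coloured by group and numbered by replicate. Infection parts the libraries along component 1 and genotype, with collection day, along component 2; replicate 2 of the infected Akh mutants lies at 16 on component 1.

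DCV infection of w1118 flies, collected 5.5 days after injection, came with a rise of many antimicrobial and heat shock genes and of the cytokine genes upd2 and upd3, and a fall of most eggshell, yolk protein and digestive enzyme genes. The cytokine upd3, a ligand of the JAK-STAT pathway, rose from 0.343 ± 0.156 to 19.2 ± 1.97 CPM (SD, n = 3 each). Frost (Fst), a cold and stress induced gene, rose from 6.34 ± 0.364 to 394 ± 51.6 CPM. The eggshell gene Cp36 fell from 396 ± 51.4 to 0.872 ± 0.0779 CPM and the yolk protein gene Yp1 from 4369 ± 127 to 37.7 ± 4.91 CPM. Cyp4g1, an enzyme of cuticular hydrocarbon synthesis that is abundant in oenocytes, fell from 1943 ± 229 to 7.31 ± 0.925 CPM. In all, 4768 of 10266 tested genes were called, 2163 higher and 2605 lower, of which 609 and 1098 changed at least 2-fold. The larger number of lower genes is not stable: with the same genes tested, 55.8% of calls were higher without replicate 1 and 55% without replicate 3 of the Akh PBS group, against 45.4% with all libraries and 46.5% and 45.5% with the filter rerun.

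Antimicrobial genes led the rise in w1118. Of 19 Imd and antimicrobial peptide genes, 14 rose and 3 fell (16 and 3 adjusted over the list alone), with a median log2 fold change of 3.14, or 3.01 with members absent from 1 group at their bound (adjusted p = 2.12e-05 at the preset correlation, adjusted p = 0.381 with an estimated correlation). Attacin-D (AttD, FBgn0038530, 3R, 17625268 to 17626086) had 1 count after PBS and 31.6 ± 1.25 CPM after DCV, a ratio of 1750 with a counting interval of 314 to 69170. The cecropin genes CecA2 and CecC also had 1 count each after PBS, with ratios of 76.0 (13.2 to 3042) and 75.0 (13.0 to 3002). Rel, the transcription factor gene of the Imd pathway, rose by log2 1.26 ± 0.05. Of 14 JAK-STAT genes 8 rose and 2 fell, the same counts adjusted over the list alone (median 0.88, adjusted p = 0.00806; adjusted p = 0.26 with an estimated correlation). Among them were upd3 (log2 5.78 ± 0.25), upd2 (5.48 ± 0.33) and Socs36E, a feedback inhibitor of the pathway (4.36 ± 0.16), while Stat92E fell (-0.36 ± 0.04). The STING-regulated genes Srg1 (6.25 ± 0.37), Srg2 (3.86 ± 0.42) and Srg3 (1.39 ± 0.26) rose, the last not with limma-voom. Dcr-2, the dicer of antiviral RNA interference, fell slightly (-0.29 ± 0.05). In that antiviral list 6 of 12 rose and 2 fell, by either adjustment (median 0.4, adjusted p = 0.029; adjusted p = 0.4 with an estimated correlation). The 21 Toll genes split, 6 higher and 6 lower by either adjustment, with PGRP-SA higher (2.12 ± 0.17) and SPE lower (-1.79 ± 0.21). The list was not called (median 0.15, adjusted p = 0.683).

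Stress genes rose as well. Of 14 heat shock genes 12 rose and none fell, by either adjustment (median 1.99, adjusted p = 4.8e-07; adjusted p = 0.26 with an estimated correlation). Among them were Hsp23 (3.41 ± 0.14), Hsp68 (4.71 ± 0.29) and the co-chaperone gene stv (2.21 ± 0.13). Hsp70Bbb (5.73 ± 0.54), Hsp70Bb (5.08 ± 0.36) and Hsp70Bc (4.78 ± 0.26) belong to a family of nearly identical copies that share reads, so which copy rose is uncertain. The JNK targets Mmp1 (2.42 ± 0.09) and puc (0.7 ± 0.05) and the JNK-regulated factor Ets21C (5.86 ± 0.17) rose. Of 14 apoptosis and JNK genes 7 rose and 2 fell by either adjustment (median 0.23, adjusted p = 0.0254; adjusted p = 0.315 with an estimated correlation). Thor, the translation inhibitor 4E-BP, rose by 1.7 ± 0.09 and the stress gene Gadd45 by 3.51 ± 0.17. Lactate dehydrogenase (Ldh) rose by 2.28 ± 0.2 while 8 of the other glycolysis genes fell, for example the hexokinase Hex-C (-2.98 ± 0.23). That list of 13 was not called (median -0.14, adjusted p = 0.0887).

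The losses in w1118 included eggshell, yolk, digestive enzyme and fat body genes. All 21 eggshell genes had negative fold changes and 19 fell (21 adjusted over the list alone; median -6.83, adjusted p = 1.35e-12; adjusted p = 0.26 with an estimated correlation). Among them were Cp38 and Cp36 (-8.82 each, ± 0.3 and 0.27), dec (-7.2 ± 0.25) and Vm32E (-7.16 ± 0.41). The 4 yolk genes all fell, by either adjustment (median -6.5, adjusted p = 0.00119; adjusted p = 0.305 with an estimated correlation): Yp1 by 6.86 ± 0.93, Yp2 (-6.34 ± 0.88), Yp3 (-6.66 ± 0.91) and the yolk receptor gene yl (-0.69 ± 0.04). DESeq2 gave no p for Yp1, Yp2 and Yp3. Of 48 digestive enzyme genes 39 fell and 2 rose (40 and 2 adjusted over the list alone; median -3.99, or -3.85 with absent members at their bound; adjusted p = 1.65e-13; adjusted p = 0.305 with an estimated correlation). The serine protease genes Jon25Biii (-9.17 ± 0.52) and Jon25Bii (-6.5 ± 0.37) fell, as did the lysozymes LysE (-8.09 ± 0.4) and LysD (-5.12 ± 0.16), which share reads with their paralogs. Of 9 fat body genes 6 fell and 1 rose by either adjustment (median -3.45, adjusted p = 0.00287; adjusted p = 0.377 with an estimated correlation): Cyp4g1 by -8.05 ± 0.37, the storage protein gene Lsp2 by -6.53 ± 0.3 and the lipophorin gene apolpp by -4.3 ± 0.27, while Fst rose. Cyp4g1 is abundant in oenocytes and Fst is stress induced, so the fat body list does not stand for fat body alone. The gut lipase gene mag fell by 7.45 ± 0.45, the acetyl-CoA carboxylase gene ACC by 2.04 ± 0.09 and the desaturase gene Desat1 by 0.9 ± 0.05. Of 16 lipid synthesis genes 11 fell and 2 rose by either adjustment (median -0.45, adjusted p = 0.000419; adjusted p = 0.26 with an estimated correlation).

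Some lists of energy metabolism and translation genes were lower. Of 69 oxidative phosphorylation genes 66 fell and 1 rose (median -0.37, adjusted p = 1.65e-16; adjusted p = 0.284 with an estimated correlation). All 11 genes of the mitochondrial genome fell (median -1.1, adjusted p = 2.63e-06; adjusted p = 0.305 with an estimated correlation). All 16 tricarboxylic acid cycle genes fell (median -0.22, adjusted p = 8.33e-06; adjusted p = 0.284 with an estimated correlation). Of 88 cytosolic ribosomal protein genes 83 fell and 1 rose (median -0.29, adjusted p = 2.44e-18; adjusted p = 0.366 with an estimated correlation). So did 13 of 19 ribosome biogenesis genes, such as Fib (-0.86 ± 0.07; list median -0.18, adjusted p = 0.00187; adjusted p = 0.26 with an estimated correlation). Of 20 muscle genes 15 fell, among them flightin (fln, -3.01 ± 0.33) and Mhc (-2.86 ± 0.28; list median -1.42, adjusted p = 8.33e-06; adjusted p = 0.387 with an estimated correlation). Odorant binding genes fell in 18 of 26 cases and rose in 2 (19 and 2 adjusted over the list alone; median -1.98, or -2.01 with absent members at their bound; adjusted p = 5.35e-06; adjusted p = 0.26 with an estimated correlation), led by Obp99a (-4.58 ± 0.12). For the other lists of this paragraph both adjustments gave the same counts.

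Other lists were called in w1118 as well. Trehalose and glycogen genes were called lower, with 7 of 10 lower and 2 higher (8 and 2 adjusted over the list alone; median -0.38, adjusted p = 0.0212; adjusted p = 0.366 with an estimated correlation). So were detoxification genes, with 53 of 115 lower and 20 higher (54 and 20 adjusted over the list alone; median -0.29, adjusted p = 0.0151; adjusted p = 0.598 with an estimated correlation), and genetic background markers, with 3 of 4 lower by either adjustment (median -1.55, adjusted p = 0.028; adjusted p = 0.369 with an estimated correlation). Histones were called higher, with 26 of 86 higher and 2 lower (25 and 2 adjusted over the list alone; median 0.37, adjusted p = 8.55e-05; adjusted p = 0.404 with an estimated correlation), and their copies share reads. DNA replication genes (11 of 22 higher by either adjustment, median 0.13, adjusted p = 0.00371) and proteasome genes (9 of 32 higher, 7 adjusted over the list alone, median 0.08, adjusted p = 0.00497) each had adjusted p = 0.614 with an estimated correlation. Neuronal genes were called higher too, with 6 of 14 by either adjustment (median 0.32, adjusted p = 0.0392; adjusted p = 0.598 with an estimated correlation). Without replicate 1 or 3 of the PBS group or replicate 2 of the DCV group they were not called (adjusted p = 0.054, 0.0638 and 0.0954).

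Of the lists not called in w1118, counts higher and lower were 3 and 5 of 12 for early female germline, 7 and 7 of 17 for haemocytes and melanisation, 4 and 4 of 9 for clock, and 5 and 11 of 22 for cuticle. They were 4 and 4 of 13 for endoplasmic reticulum stress, 2 and 5 of 14 for beta oxidation, 4 and 4 of 12 for Akh and insulin signalling, 3 and 3 of 15 for photoreceptors, 2 and 5 of 15 for redox, and 6 and 6 of 18 for tRNA synthetases. Each of these was the same adjusted over the list alone. For ATF4 and serine synthesis they were 4 and 8 of 13 (4 and 9 over the list alone), for autophagy 7 and 1 of 23 (7 and 0), for lipid mobilisation 2 and 3 of 10 (3 and 3) and for the mitochondrial ribosome 0 and 10 of 73 (0 and 6). The share of counts from the mitochondrial genome was 1.65% ± 0.08 after PBS and 1.05% ± 0.06 after DCV (SD, n = 3 each).

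**Figure D2:**
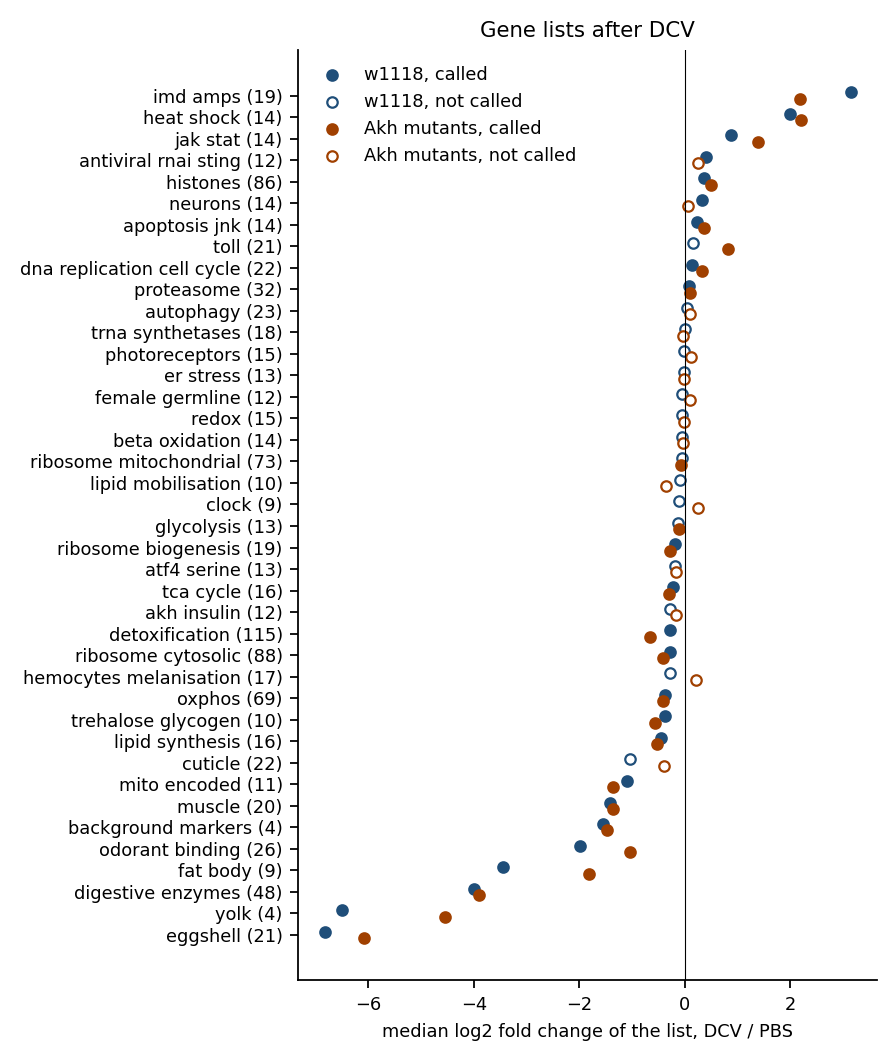
Median log2 fold change (DCV over PBS, horizontal) of each tested list in w1118 (blue) and Akh mutants (brown), filled where camera with the preset correlation called the list and open where it did not, with the number of tested members in brackets. Eggshell, yolk, digestive and fat body genes lie lowest in both genotypes, and Imd and heat shock genes highest.

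Akh mutants, collected 3.5 days after injection, showed losses and gains in many of these genes, by different amounts for some. Fst rose from 5.07 ± 2.26 to 1004 ± 142 CPM and upd3 from 1.26 ± 0.351 to 16.8 ± 0.672 CPM, while Cp36 fell from 464 ± 92.6 to 1.19 ± 0.521 CPM and Cyp4g1 from 2556 ± 106 to 43.1 ± 19.4 CPM (SD, n = 3 each). Yp1 fell from 5875 ± 458 to 253 ± 304 CPM (SD, n = 3 each), with 57.0, 603 and 99.2 CPM in replicates 1, 2 and 3, replicate 2 being the library nearest to the PBS groups. In all, 6032 of 10266 genes were called, 3539 higher and 2493 lower, of which 385 and 1086 changed at least 2-fold. In a fit of these 6 libraries alone 48.8% of 4955 calls were higher, against 58.7% with all 12 libraries.

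Immune genes rose in the mutants, and here the Toll list was called. Of 21 Toll genes 14 rose and 1 fell (15 and 1 adjusted over the list alone; median 0.82, adjusted p = 0.0108; adjusted p = 0.529 with an estimated correlation). Among them were PGRP-SA (2.23 ± 0.17), the effector peptide gene BomBc1 (2.05 ± 0.26), spz, the ligand of Toll (0.54 ± 0.05), and the inhibitor gene cact (0.51 ± 0.04). Of 19 Imd and antimicrobial peptide genes 14 rose and 1 fell (15 and 1 adjusted over the list alone; median 2.18, adjusted p = 0.00131; adjusted p = 0.492 with an estimated correlation). These were led by AttD (6.03 ± 0.31), CecA2 (5.28 ± 0.45) and CecB (4.58 ± 0.61). Of 14 JAK-STAT genes 7 rose and 2 fell by either adjustment (median 1.38, adjusted p = 0.0149; adjusted p = 0.262 with an estimated correlation). The cytokine gene upd2 was at 6.34 ± 0.3, Socs36E at 3.97 ± 0.14, upd3 at 3.73 ± 0.21 and the receptor gene dome at 0.63 ± 0.03. Of 14 heat shock genes 12 rose and 1 fell by either adjustment (median 2.21, adjusted p = 1.38e-05; adjusted p = 0.262 with an estimated correlation): Hsp68 rose by 5.35 ± 0.26 and the nearly identical copies Hsp70Bbb by 7.35 ± 0.58 and Hsp70Ab by 6.12 ± 0.25. The JNK genes puc (1.35 ± 0.05), Jra (0.71 ± 0.06) and Mmp1 (2.55 ± 0.08) and the factor Ets21C (5.89 ± 0.15) rose. Their list had 8 of 14 higher and 1 lower by either adjustment (median 0.36, adjusted p = 0.0203; adjusted p = 0.265 with an estimated correlation). CG43095 had 3 counts after PBS and rose by a ratio of 198 (67.4 to 963). DNA replication and cell cycle genes rose in 21 of 22 cases by either adjustment, by small amounts such as CycB3 (0.45 ± 0.05; list median 0.32, adjusted p = 1.25e-05; adjusted p = 0.448 with an estimated correlation).

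Eggshell genes fell in 19 of 21 cases in the mutants (21 adjusted over the list alone; median -6.09, adjusted p = 2.15e-13; adjusted p = 0.262 with an estimated correlation): Cp38 by -9.3 ± 0.29, Vm32E by -8.21 ± 0.39 and Cp7Fc by -7.65 ± 0.28. The 4 yolk genes fell by either adjustment (median -4.54, adjusted p = 0.0033; adjusted p = 0.267 with an estimated correlation). Digestive enzyme genes fell in 37 of 48 cases and rose in 7 (38 and 7 adjusted over the list alone; median -3.91, adjusted p = 1.39e-10; adjusted p = 0.271 with an estimated correlation). Among them were Jon25Bii (-8.38 ± 0.28) and iotaTry (-2.9 ± 0.2). Of 9 fat body genes 8 fell and 1 rose by either adjustment (median -1.81, adjusted p = 0.00157; adjusted p = 0.278 with an estimated correlation). Detoxification genes fell in 64 of 115 cases and rose in 12 (65 and 12 adjusted over the list alone; median -0.67, adjusted p = 1.6e-07; adjusted p = 0.265 with an estimated correlation). Examples are the cytochrome P450 genes Cyp4d1 (-4.48 ± 0.33) and Cyp6w1 (-2.56 ± 0.22). Oxidative phosphorylation genes (68 of 69 lower, 1 higher, median -0.41, adjusted p = 1.32e-20), mitochondrial genome (11 of 11 lower, median -1.37, adjusted p = 8.59e-08) and cytosolic ribosome (85 of 88 lower, median -0.41, adjusted p = 2.61e-26; 85 lower and 1 higher adjusted over the list alone) each had adjusted p = 0.262 with an estimated correlation. The histone gene His2A:CG33808 was at least 611-fold lower after DCV, where it had 0 counts, but histone copies share reads and limma-voom did not call it. The proteasome list (16 of 32 higher by either adjustment, median 0.1, adjusted p = 0.0182; adjusted p = 0.664 with an estimated correlation) was not called with RLE size factors (adjusted p = 0.126) or without replicate 1 of the PBS (0.0734) or DCV group (0.106). Further lists called lower in the mutants were tricarboxylic acid cycle (15 of 16, median -0.3, adjusted p = 1.46e-06), odorant binding (17 of 26, 1 higher, median -1.05, adjusted p = 2.34e-05), ribosome biogenesis (13 of 19, 1 higher, median -0.28, adjusted p = 0.000144) and glycolysis (7 of 13, median -0.11, adjusted p = 0.0137), with the same counts over the list alone. Lipid synthesis (10 of 16, 4 higher, 10 and 5 over the list alone, median -0.52, adjusted p = 0.00468) and mitochondrial ribosome (17 of 73, 14 over the list alone, median -0.07, adjusted p = 0.00302) were lower too, and these 6 lists each had adjusted p = 0.262 with an estimated correlation. Muscle (16 of 20 lower, median -1.36, adjusted p = 1.38e-05; adjusted p = 0.39 with an estimated correlation) was called as well. So were trehalose and glycogen (6 of 10 lower, 1 higher, 7 and 2 over the list alone, median -0.57) and background markers (3 of 4 lower, median -1.48), each with adjusted p = 0.0137, and adjusted p = 0.267 with an estimated correlation. Histones were called higher (34 of 86, 4 lower, 34 and 3 over the list alone, median 0.49, adjusted p = 0.00288; adjusted p = 0.531 with an estimated correlation). The mitochondrial share of counts was 2.43% ± 0.13 after PBS and 1.4% ± 0.14 after DCV (SD, n = 3 each).

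Fold changes in both genotypes went together across genes (Pearson r = 0.801, Spearman rho = 0.666, across 10266 genes, which are not independent replicates). Of the genes called, 1543 were higher in both, where independence gives 746, and 1869 were lower in both, where it gives 633. Only 43 were higher in w1118 and lower in Akh mutants, and 189 the reverse.

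**Figure D3:**
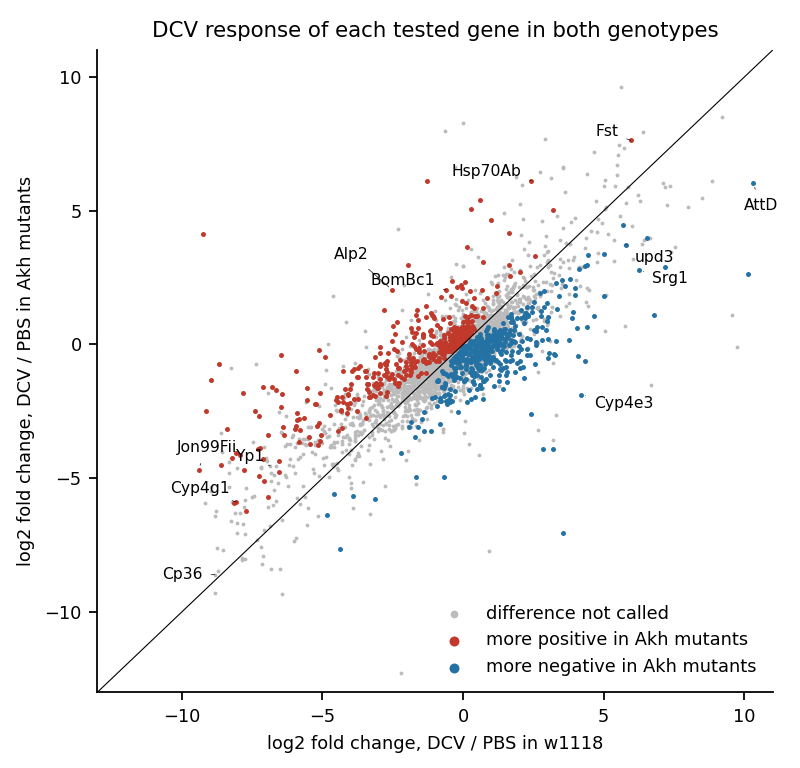
Log2 fold change after DCV in w1118 (horizontal) and in Akh mutants (vertical), one point per tested gene with the line of equal change. Red and blue points are the 1524 and 496 genes whose response differed in the interaction test; AttD, Srg1 and Cyp4e3 lie below the line, and Hsp70Ab, BomBc1 and Jon99Fii above it.

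The response to DCV differed between the genotypes, each at its own collection day, in 2020 genes. Among others, the haemocyte receptor genes Sr-CI and eater and the maltase Mal-A8 had more positive changes in Akh mutants than in w1118. Srg1, GstD2, AttD and upd3 had more negative ones. The P450 gene Cyp4e3 rose in w1118 from 3.12 ± 0.826 to 57.0 ± 15.3 CPM, whereas in Akh mutants it had 63.1 ± 8.74 CPM after PBS and 17.3 ± 3.72 after DCV (SD, n = 3 each), a log2 difference of -6.06 ± 0.36. The alkaline phosphatase gene Alp2 had 44.9 ± 7.04 and 7.82 ± 0.111 CPM in w1118 and 17.0 ± 7.82 and 69.6 ± 16.3 CPM in Akh mutants (SD, n = 3 each), a difference of 4.56 ± 0.45. Positive differences numbered 1524 and negative ones 496, or 75.4% positive, of which 221 and 253 were at least 2-fold. The balance of the 2-fold genes depends on the infected mutants, with 338 and 202 without their replicate 1 and 211 and 394 without replicate 2. With RLE size factors 1550 genes were called and 58.1% were positive, and with DESeq2 1757 and 57.5%. The most frequent class, 752 genes, was higher in Akh mutants and not called in w1118.

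Immune genes were on both sides of this difference. Haemocyte genes Sr-CI (2.61 ± 0.32), eater (2.48 ± 0.45) and Hml (2.1 ± 0.35) were more positive in Akh mutants, and Sr-CI and Hml fell in w1118 by -2.94 ± 0.26 and -2.7 ± 0.27. In the haemocyte and melanisation list 4 of 17 were more positive and 1 more negative (5 and 3 adjusted over the list alone, median -0.1, adjusted p = 0.913). Of 21 Toll genes 6 were more positive (11 and 1 negative adjusted over the list alone), among them BomBc1 (2.66 ± 0.36), Dif (0.87 ± 0.12) and Tl (0.64 ± 0.08), without a call for the list (median 0.65, adjusted p = 0.0602). AttD (-4.28 ± 0.92, not called without replicate 1 of the Akh PBS group, adjusted p = 0.0814, and of a poorly determined size with 1 count in w1118 after PBS), upd3 (-2.05 ± 0.36), Srg1 (-3.47 ± 0.52) and Srg2 (-2.87 ± 0.52) were more negative, Srg2 not with limma-voom. For upd3, Srg1 and Srg2 the mutant level after PBS was already higher, at 1.26 ± 0.351 against 0.343 ± 0.156 CPM, 1.17 ± 0.0623 against 0.289 ± 0.256 CPM and 38.0 ± 11.8 against 1.32 ± 0.206 CPM (SD, n = 3 each). Srg2 was higher in the mutants after DCV as well, at 75.7 ± 25.5 against 19.3 ± 2.19 CPM (SD, n = 3 each). JNK genes puc (0.65 ± 0.07) and Jra (0.4 ± 0.08) were more positive.

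Metabolic genes differed too. The maltases Mal-A8 (3.16 ± 0.3), Mal-A7 (3.2 ± 0.34) and Mal-A6 (2.76 ± 0.34) were more positive in Akh mutants. Their digestive list had 12 of 48 more positive and 2 more negative (14 and 3 adjusted over the list alone, median 0.94, adjusted p = 0.494). The serine protease genes Jon99Fii (4.72 ± 1.21) and Jon99Ciii (4.01 ± 1.04) were called as well, but share reads with paralogs. With limma-voom they were not called (adjusted p = 0.0669 and 0.118), nor without 7 and 10 of the 12 single libraries. Detoxification genes were called more negative (21 of 115 against 10 positive, 23 and 11 adjusted over the list alone, median -0.08, adjusted p = 0.00138; adjusted p = 0.982 with an estimated correlation). GstD2 was at -3.42 ± 0.48, GstD5 at -3.18 ± 0.59 and GstD9 at -1.99 ± 0.19. Ldh (-2.03 ± 0.27) and the sugar-responsive factor gene sug (-1.64 ± 0.34) were more negative. Cyp4g1 (2.16 ± 0.44), the transferrin gene Tsf1 (2.24 ± 0.37) and Fst (1.67 ± 0.37) were more positive. Cytosolic ribosomal protein genes (12 of 88 more negative, 3 more positive; 5 and 2 adjusted over the list alone; median -0.1, adjusted p = 7.51e-08) were called more negative. So were oxidative phosphorylation genes (2 of 69 more negative, 1 more positive; 1 and 0 adjusted over the list alone; median -0.06, adjusted p = 0.00141). DNA replication genes were more positive (8 of 22; 11 adjusted over the list alone; median 0.2, adjusted p = 0.00423). Each of these 3 lists had adjusted p = 0.982 with an estimated correlation. The light receptor gene ninaE (0.95 ± 0.11) and the arrestin genes Arr1 (0.95 ± 0.12) and Arr2 (0.72 ± 0.11) were more positive. Akh (-0.96 ± 1.08) and AkhR (-0.9 ± 0.36) were not called. With the same genes tested, an alternative chosen after the data were seen, 1122 genes were called without replicate 1 and 1260 without replicate 3 of the Akh PBS group, against 1492 and 1659 with the filter rerun as planned.

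**Figure D4:**
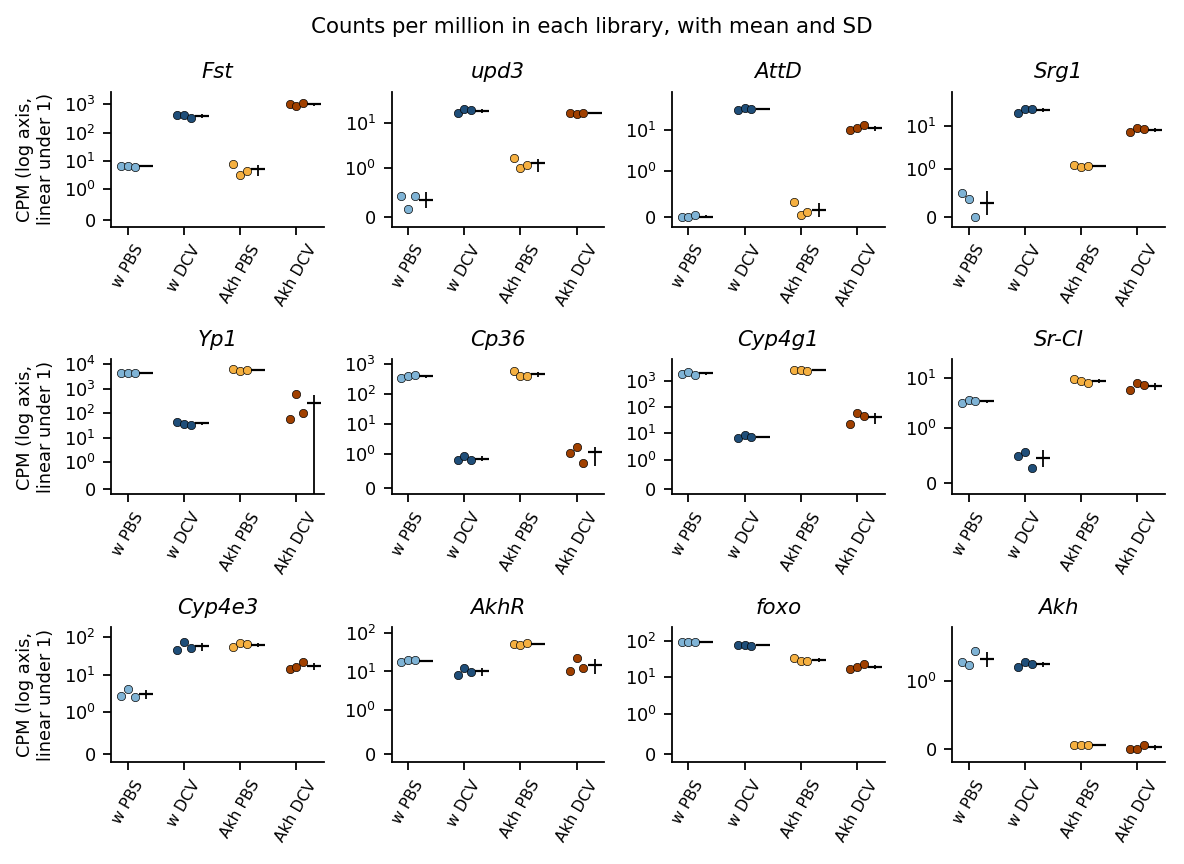
CPM of 12 genes in each library (points; vertical log axis, linear under 1), with the mean and SD of the 3 libraries of each group beside them. Fst and upd3 rise in both genotypes, Yp1 and Cp36 fall in both, and Akh is at or near 0 in the mutant libraries.

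After PBS, 5885 of 10266 genes differed between Akh mutants at 3.5 days and w1118 at 5.5 days, 2686 higher and 3199 lower in the mutants, of which 729 and 284 differed at least 2-fold. The larger number of lower genes depends on scaling: 53.4% of 5722 calls were higher with RLE size factors and 53.3% of 5480 with DESeq2, against 45.6% with TMM. The receptor gene of the hormone, AkhR (FBgn0025595, 2L, 6711286 to 6716186), was higher in the mutants by log2 1.43 ± 0.25 (51.7 ± 3.31 against 19.1 ± 1.22 CPM, SD, n = 3 each). The transcription factor gene foxo, a target of insulin signalling, was lower by 1.61 ± 0.09 on the log2 scale (29.9 ± 3.78 against 91.4 ± 1.7 CPM, SD, n = 3 each; 3R, 14056945 to 14087978). Near all-or-none differences included P450 genes in both directions. Cyp12d1-d had 0 counts in w1118 and was at least 715-fold higher in the mutants, but 58.3% of its values are not whole, so it shares reads with another gene. Cyp6a17 was lower by a ratio of 1328 (238 to 52490), with 16.7% of its values not whole.

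Other genes differed as well. Thor (1.19 ± 0.09), sug (1.01 ± 0.24), the perilipin gene Lsd-1 (1.37 ± 0.27), Apoltp (0.96 ± 0.25) and apolpp (0.91 ± 0.23) were higher in the mutants, and Lsd-2 (-0.33 ± 0.05), the triglyceride lipase gene bmm (-0.15 ± 0.04, not with DESeq2) and Hsl (-0.25 ± 0.05) lower. Ilp3 was higher by a ratio of 8.74 (2.68 to 45.1), while Ilp2 (0.49 ± 0.32), Ilp6 (0.19 ± 0.28), InR (-0.01 ± 0.06) and mag (0.08 ± 0.25) were not called. The trypsin genes epsilonTry (10.96 ± 0.94) and betaTry (10.07 ± 0.52) were higher and gammaTry (-3.76 ± 0.79) lower, with reads shared among some of these neighbours. Genes lower in the mutants included tut (-5.79 ± 0.2), the cell polarity gene l(2)gl (-3.59 ± 0.1) and Dscam4 (-3.55 ± 0.13), and w (-1.81 ± 0.5), the eye colour gene mutated in w1118. Imd and antimicrobial genes were higher in 11 of 19 cases by either adjustment (median 2.22, or 2.02 with absent members at their bound; adjusted p = 0.00202; adjusted p = 0.857 with an estimated correlation).

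Of the other lists called after PBS, higher in the mutants were cytosolic ribosome (76 of 88, 2 lower, 77 and 2 adjusted over the list alone, median 0.21, adjusted p = 7.4e-13), oxidative phosphorylation (58 of 69, 3 lower, 59 and 3 over the list alone, median 0.29, adjusted p = 4.78e-10) and mitochondrial genome (11 of 11, median 0.61, adjusted p = 0.000135). So were muscle (16 of 20, median 0.79, adjusted p = 0.000417), odorant binding (13 of 26, 2 lower, median 0.76, adjusted p = 0.00157), tricarboxylic acid cycle (11 of 16, 1 lower, 12 and 1 over the list alone, median 0.18, adjusted p = 0.00532) and haemocytes (11 of 17, 2 lower, median 0.81, adjusted p = 0.0179). Photoreceptors (5 of 15, 4 over the list alone, median 0.27, adjusted p = 0.0179) were not called without replicate 3 of w1118 PBS (0.0535). Eggshell genes (6 of 21, median 0.88, adjusted p = 0.0298) were not called with RLE size factors (0.0811) or without replicate 1 of w1118 PBS (0.097) or of Akh PBS (0.0818). Lower were DNA replication (19 of 22, 20 over the list alone, median -0.27, adjusted p = 2.85e-05) and histones (54 of 86, 12 higher, 54 and 13 over the list alone, median -1.08, adjusted p = 8.69e-05), whose reads are shared among copies. Each of these had adjusted p = 0.857 with an estimated correlation.

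After DCV, 5095 genes differed between the genotypes, 2915 higher and 2180 lower in Akh mutants, of which 927 and 359 differed at least 2-fold. In a fit of these 6 libraries alone 49.8% of 4406 calls were higher, against 57.2% with all 12. All 4 yolk genes were higher in the mutants (median 2.34), without a call for the list (adjusted p = 0.0998). Much of this rests on replicate 2 of infected mutants: without it Yp1 was higher by 1.05 ± 0.22 instead of 2.75 ± 0.8, and Yp2 and Yp3 were not called (adjusted p = 0.155 and 0.0526). Of 48 digestive enzyme genes 20 were higher and 5 lower (22 and 5 adjusted over the list alone; median 1.53, or 1.48 with absent members at their bound; adjusted p = 0.00532; adjusted p = 0.76 with an estimated correlation). The immune genes PGRP-SB1 (4.65 ± 0.57) and Dro, encoding drosocin (4.45 ± 0.65), were higher, as were Ilp8 (2.64 ± 0.43), upd2 (1.3 ± 0.19), Lip4 (0.72 ± 0.15) and apolpp (2.1 ± 0.26). After PBS the mutant means were already higher for PGRP-SB1 (18.4 ± 3.63 against 5.2 ± 0.657 CPM) and Dro (8.24 ± 3.12 against 0.163 ± 0.196 CPM, SD, n = 3 each). The gene foxo was lower again (-1.96 ± 0.1), and w too (-2.97 ± 0.57). AkhR (0.53 ± 0.27), bmm (-0.06 ± 0.04) and mag (1.86 ± 0.74) were not called. CG42857 (-8.17 ± 0.34), CG11825 (-8.01 ± 0.19), Cyp6a17 (-7.96 ± 0.31) and Tektin-C (-6.66 ± 0.41) were lower too. Of the features without a gene name, 1 was at least 208-fold higher.

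The other lists called after DCV were higher in the mutants for oxidative phosphorylation (46 of 69, 5 lower, 47 and 5 over the list alone, median 0.22, adjusted p = 0.000102), muscle (15 of 20, 1 lower, 17 and 1 over the list alone, median 0.97, adjusted p = 0.0016) and odorant binding (16 of 26, 1 lower, median 1.79, adjusted p = 0.00542). Fat body (6 of 9, 7 over the list alone, median 1.35, adjusted p = 0.017), photoreceptors (10 of 15, 1 lower, median 0.56, adjusted p = 0.0179), mitochondrial genome (8 of 11, median 0.45, adjusted p = 0.0242) and clock (6 of 9, 6 and 1 lower over the list alone, median 0.56, adjusted p = 0.0302) were higher as well. So were Imd and antimicrobial genes (12 of 19, 2 lower, 14 and 2 over the list alone, median 1.71) and apoptosis and JNK genes (8 of 14, 9 over the list alone, median 0.31), each with adjusted p = 0.0379, and tricarboxylic acid cycle genes (10 of 16, 1 lower, median 0.15, adjusted p = 0.0492). Histones were lower (56 of 86, 17 higher, 57 and 18 over the list alone, median -1.02, adjusted p = 1.44e-06). Each had adjusted p = 0.76 with an estimated correlation. Cytosolic ribosome genes were higher (47 of 88, 8 lower, 48 and 8 over the list alone, median 0.13, adjusted p = 0.00199; adjusted p = 0.812 with an estimated correlation). DNA replication genes were lower (11 of 22, 2 higher, median -0.12, adjusted p = 0.0277; adjusted p = 0.804 with an estimated correlation). Without replicate 2 of infected Akh mutants the Imd (adjusted p = 0.0616), apoptosis (0.0529), DNA replication (0.114) and tricarboxylic acid cycle (0.114) lists were not called. Without replicate 3 of infected w1118 the Imd (0.0564), apoptosis (0.0593) and DNA replication (0.0548) lists were not called. Apoptosis was also not called without replicate 3 of infected Akh mutants (0.0615), nor the tricarboxylic acid cycle list without replicate 1 of w1118 PBS (0.0528) or replicate 1 (0.0867) or 2 (0.073) of infected w1118, nor with the replicate number as a block (0.0598).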

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

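The tests of eggshell and yolk protein genes, of the share of positive differences, of shared reads and of collection day were chosen after the results were seen. The test of a segment around Akh and the counts over other splits were planned.

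The response to DCV differed between the genotypes in 2020 genes by an interaction test. Of 86 genes named for the infection responses and their difference, 49 differed, 31 more positive and 18 more negative in Akh mutants. Some of the 86 were named because this same test called them, so that share is not a result. Over all 10266 tested genes the share was 19.7%. Among the positive were the gut and haemocyte genes Alp2 (4.56), the maltases Mal-A7 (3.2), Mal-A8 (3.16) and Mal-A6 (2.76), the receptors Sr-CI (2.61) and eater (2.48), and Hml (2.1). The proteases Jon99Fii (4.72) and Jon99Ciii (4.01) and the heat shock gene Hsp70Ab (3.7) were positive too but share reads with paralogs. Immune and secreted genes followed, with BomBc1 (2.66), Tsf1 (2.24), Dif (0.87), Tl (0.64), spz (0.33), cact (0.28), dome (0.33), Stat92E (0.25) and Dcr-2 (0.32). Genes listed under fat body, muscle or eye were Cyp4g1 (2.16), Lsp2 (1.77), Fst (1.67), apolpp (1.18), fln (1.39), ninaE (0.95), Arr1 (0.95) and Arr2 (0.72). The rest were the JNK genes puc (0.65) and Jra (0.4), the yolk receptor yl (0.34) and the cyclin CycB3 (0.24). Some of these calls were unstable: apolpp was lost under 13 other settings (10 of them with a library left out), Jon99Ciii under 12 (10), Jon99Fii under 9 (7), fln under 9 (8), Lsp2 under 6 (5) and CycB3 under 4 (2).

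On the negative side lay Cyp4e3 (-6.06), AttD (-4.28), Srg1 (-3.47), Srg2 (-2.87), Srg3 (-1.42) and upd3 (-2.05). Glutathione transferases were GstD2 (-3.42), GstD5 (-3.18) and GstD9 (-1.99). Metabolic and stress genes were Ldh (-2.03), sug (-1.64), Hsp23 (-1.6), Gadd45 (-1.09), Thor (-0.56) and Desat1 (-0.42). The others were the eggshell gene Cp7Fc (-3.29), iotaTry (-1.05) and Obp99a (-1.01). AttD, Srg2, Srg3, Cp7Fc and Obp99a each lost the call under 1 setting. The value for AttD rests on 1 count in w1118 after PBS, so its size is poorly determined. Of the lists, DNA replication had a median of 0.2, cytosolic ribosome -0.1, detoxification -0.08 and oxidative phosphorylation -0.06, called by camera at the preset correlation (adjusted p = 0.00423, 7.51e-08, 0.00138 and 0.00141; adjusted p = 0.982 with an estimated correlation for each). Of 100 relabellings of treatment within genotype, the real one included, 2 gave as many genes, with a highest other value of 3109 and then 2009 and 1922. This does not exclude chance, although the share is under 0.05 and the plan took such a share to exclude it. A relabelling that mixes the treatments in both genotypes moves the response to DCV into the spread within groups. One that mixes them in 1 genotype leaves the response of the other to count as a difference. The relabellings with 3109, 2009 and 1922 kept the Akh mutant treatment groups apart and mixed the w1118 ones, which points to a structure of the samples, the large response to DCV itself.

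For the other comparisons, 10 splits of 6 libraries are too few for a share under 0.05. In each, 1 of the 10 splits, the real one, gave as many genes. Real values were 4768 for DCV in w1118, 6032 for DCV in Akh mutants, 5885 for the genotypes after PBS and 5095 after DCV. The highest other split gave 0 in each by edgeR. Splits that mix the groups move their difference into the spread within groups, so these counts do not exclude chance.

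The eggshell genes and Yp1, Yp2 and Yp3 were lower after DCV in both genotypes. A smaller share of the whole ovary would lower early germline genes as well. Their median was -0.05 in w1118 (members from -0.84 to 0.36), against eggshell genes from -8.82 to -3.97, and 0.09 in Akh mutants (members from -0.5 to 0.48), against -9.3 to -3.12. Scaling moves all genes alike and cannot part these 24 genes from the germline ones, but their medians differed by -6.7 in w1118 and -6 in Akh mutants, with no overlap. The receptor gene yl (-0.69 in w1118) lies within the germline range and is not covered. A candidate explanation that stays open is a stop of late egg chamber and fat body transcripts during infection, which was not tested.

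The difference of responses had more positive than negative calls. With RLE size factors 58.1% were positive, against 75.4% with TMM, so library scaling may account for much of this share. The bounds of that test were set with this value and the next in view. Without the less affected replicate 2 of infected Akh mutants 69.2% were positive, still the larger share. A part played by that library is not excluded. With the same genes tested, 45% were positive without replicate 1 of the Akh PBS group and 43.8% without replicate 3, but 76.4% without either in turn when the filter was rerun as planned. Collection day cannot be told apart from genotype, since the genotypes shared 0 days.

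Near all-or-none genotype differences, at least 16-fold after both PBS and DCV, numbered 32 genes with a position, 20 higher and 12 lower in the mutants, and 18 features without one. A chromosome segment carried along with the Akh mutation, if it were the main source, would hold most of them. Of the 32, 3 (9.4%) lay within 5 Mb of Akh, against 7.9% of tested genes (Fisher exact p = 0.738). Such a segment may still account for those 3, and the 18 features without a position could not be placed. Shared reads stay open as well: 13 of the 32 (40.6%) had values that are not whole in the genotype that expresses them, against 19.2% of tested genes in w1118 libraries and 19% in mutant ones. The bounds of that test were set with such values in view. Collection day stays open with 0 shared days, and differences in strain background, which the design does not separate from Akh, were not tested.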

How the results depend on the processing

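Omission of a library while the same genes were tested was chosen after the data were seen. Of 146 values of the main counts, similarity and list results under other settings, 133 stayed within the spread or 1.5 times, as did 427 of those with 1 library left out. The cause of the changes below was not tested.

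For the difference of responses, positive genes numbered 901 with RLE size factors and 1011 with DESeq2 (1524 with TMM in edgeR), and negative ones 746 with DESeq2 (496). The correlation of the responses was 0.827 with limma-voom, 0.603 without a low-count filter and 0.851 with a filter of 5 CPM (0.801). Camera with an estimated correlation called 0 lists in each of the 5 comparisons (24, 25, 4, 12 and 14 at the preset correlation), with 6, 6, 0, 0 and 0 lists at an unadjusted p under 0.05. Fry called 0 lists for the difference (6 unadjusted) and 25 for the genotypes after DCV.

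With 1 library left out, the difference had 1122 (without Akh PBS replicate 1, same genes) to 2448 genes (without Akh DCV replicate 2), and 1260 without Akh PBS replicate 3. With the filter rerun, the range was 1350 to 2441. Positive genes ranged from 505 to 1695 (1012 to 1690 with the filter rerun) and negative ones from 312 (without w1118 DCV replicate 2) to 753 (without Akh DCV replicate 2; 751 with the filter rerun). Without Akh PBS replicates 1 and 3 in turn, 76.4% of 1492 and 76.4% of 1659 genes were positive with the filter rerun, but 45% of 1122 and 43.8% of 1260 with the same genes tested. The share of higher genes for DCV in w1118 then moved too, from 45.4% to 55.8% and 55%, though none of its libraries was left out. It moved from 58.7% to 48.6% and 49.3% for DCV in Akh mutants, from 45.6% to 54.8% and 54.4% for the genotypes after PBS and from 57.2% to 49% and 49% after DCV. Genes lower in mutants after PBS ranged from 2114 (without Akh PBS replicate 1) to 3303, the correlation from 0.769 to 0.804 (0.783 and 0.793 at the inner ends), and lists for the difference from 4 to 9 (without Akh DCV replicate 1).

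Values of all genes given by the naming rule numbered 4346 under other settings. Of these, 4237 kept their side of the threshold, 88 lost the call, 21 gained one and 0 reversed. A change of direction counted as a reversal only for a gene called with the main settings or the altered ones. With a library left out, 6494 of 6792 kept their side, 275 lost the call, 22 gained one and 1 reversed. The reversal was Apoltp between genotypes after DCV, at 0.28 without Akh DCV replicate 1 and -0.28 without replicate 2 (-0.01 with all libraries, not called). For the 79 list calls at the preset correlation, 155 of 158 values with RLE size factors or the replicate block kept the call. With a library left out 929 of 948 did. These counts leave out fry and camera with an estimated correlation, which called 0 lists. At this depth the receptor gene AkhR in w1118 (-0.91) was not called without w1118 PBS replicate 2 (adjusted p = 0.0517) or w1118 DCV replicate 1 (0.0624) or 3 (0.0571).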

Other observations

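Copia-annotated features, an addition of the authors to the gene table, rose after DCV in w1118 and not in Akh mutants. Copia is a retrotransposon. DNA integration was among the terms over-represented in genes at least 2-fold higher in w1118, with 9 of 17 genes against 0.8 expected (adjusted p = 6.22e-06, hypergeometric test). Whether copia-annotated features are among these genes was not checked, so the term is not separate support. Other terms were response to wounding (10 of 28) and response to hypoxia (9 of 25). Among genes at least 2-fold lower in w1118 were 24 of 46 with ecdysteroid 22-kinase activity (adjusted p = 1.57e-10) and 12 of 14 fatty acid elongases. These lower terms were over-represented in Akh mutants too, with 20 of 46 and 12 of 14. So were wounding (6 of 28) and hypoxia (7 of 25) among their higher genes. These terms, and the test of copia, were chosen after the results were seen.

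The summed counts of 9 copia-annotated features went from 245 ± 11.6 to 502 ± 60.2 CPM in w1118 and from 184 ± 10.8 to 172 ± 16.5 CPM in Akh mutants (SD, n = 3 each). Log2 changes were 1.03 ± 0.09 (adjusted p = 7.03e-06 in edgeR) and -0.11 ± 0.09 (0.355). The responses differed by -1.14 ± 0.13 (adjusted p = 0.000345 in edgeR). This test was chosen after the results were seen. For these summed features, the values argue against a rise of the same size in both genotypes, each at its own collection day. The hypothesis that the rise in w1118 may depend on Akh cannot be set apart from collection day, at 5.5 and 3.5 days, or from strain background. After PBS the summed counts were already lower in Akh mutants (log2 -0.41 ± 0.09, adjusted p = 0.00342 in edgeR).

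Few testis and seminal fluid genes passed the filter, 2 of 16 and 2 of 51, with highest CPM in any library of 20.8 and 1.81. Eggshell and yolk transcripts were abundant after PBS. The sex of the flies is not given in the labels.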
